A study of Gallus gallus with 16 samples.

How the data were processed

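Livers of 16 male broiler chickens (Gallus gallus) were sampled at day 21, 4 from each of the diets A, E, F and H, as the sample characteristics give them. The series' design text says that chickens were collected per dietary group, so each array was taken as 1 bird and the birds as the replicates. Replicates were numbered in accession order within a diet, and these numbers only name birds. Per the labels' protocols, total RNA was isolated with Qiazol, treated with DNase, purified on columns, transcribed with a whole-transcript expression kit and labelled with biotin for 1-colour Affymetrix arrays.

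The deposited values are on a log2 scale, as their range of 0.93 to 14.63 shows. The array software GCOS 1.1.1 is named per the submitters' processing notes. The background correction, summarization and normalization by which the authors made these log2 values are not given in the sources used here. The array medians lie close together (6.11 to 6.21) and the distributions are not identical, with standard deviations of 2.10 to 2.21, so that no quantile normalization over these arrays was the last step. The values are not centred per gene, and a log2 difference of 1 was read as a 2-fold difference. The table has 20804 features on 16 arrays with 0 missing values. Of these features, 12300 (59.1%) have 1 gene symbol in the platform annotation, 256 have several and 8248 are unnamed here. No gene was named from a feature with several symbols. Entrez IDs were matched to the RefSeq gene table of assembly GRCg7b, which held 11727 of the named features and changed 0 symbols. The genome build of the array design was not given, so no coordinates are printed, and that table served only for names and for the genomic span of a gene from start to end. Of all features, 1644 share identical values on all arrays with another, 18 of them named. How far a signal lies above background was not known. The 20th percentile of all values served as a mark for dim features.

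One linear model per feature with a mean for each diet was fitted to all 16 arrays in limma 3.58.1 (R 4.3.3), so that the diets shared 1 estimate of the spread with 12 residual degrees of freedom and a prior of 4.12. The 6 pairwise differences were tested two-sided with empirical Bayes moderation, and an F test covered all diets together. Benjamini-Hochberg adjustment ran over all 20804 features, with a threshold of 0.05. Errors of differences are standard errors from this model, and levels are means with their SD over 4 birds. No unadjusted p of a single gene is printed. The number of arrays limits the precision, with a median standard error of 0.216. The procedure was tested on simulated data of the diet E and diet A comparison with 200 of the 20804 features changed. It recovered 4% of 50 features at a true 1.41-fold change, 58% at 2-fold, 92% at 4-fold and 100% at 8-fold, with 5 false calls in all. The simulated noise was drawn independently for each feature, without correlation between genes, so these rates may not carry over to the real arrays.

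Gene lists for liver metabolism, stress, immunity, growth and the cell types a liver sample can hold were fixed before the data were examined, 34 in all, and so were the comparisons, the rule for naming genes and the first set of alternative settings. The lists were written from general knowledge of gene function, not from these arrays. Each gene was represented by its feature with the highest mean, which gave 11528 genes as the background, and 33 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01. This test compares a list with all other genes. Each list was tested again with a correlation estimated from the residuals, and 0 lists were called in any comparison, with 3, 0, 0, 2, 1 and 1 at an unadjusted p under 0.05 in E minus A, F minus A, H minus A, E minus F, H minus E and H minus F. limma's fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 0 lists, with 2, 0, 3, 1, 1 and 1 at an unadjusted p under 0.05. Of the intestine and pancreas markers 21 of 30 lay above the 20th percentile in these livers on average, and 3 are also in another list. For the T and NK cell, macrophage, bile duct and stellate cell markers this was 24 of 25, 20 of 21, 18 of 19 and 32 of 32.

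The text names, for each difference from diet A, the 10 genes with the smallest p, since no gene passed adjustment and the rule then fills up to 10, for each other comparison 6, and for the F test 6, each with 1 symbol that is no placeholder. The rule adds up to 4 members of each shifted list by p in the list's direction, of which the first 3 were tabulated for differences from diet A and the first 2 otherwise, and the text gives most of these. These are given as values, not as changes. Chance levels for the lists and for the likeness of differences came from 100 simulated data sets that keep the residual covariance between genes. Correlations across birds have permutation p values from 100000 permutations. The random block was fitted with statmod 1.5.0.

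The first set of alternative settings was quantile normalization, centring on array medians, leaving out the dimmest 25% of features and a floor at the 20th percentile. It also held the title number block as a covariate, neighbouring title numbers as a random block, array quality weights, a trended and robust prior, fits of 2 diets alone, the mean of a gene's features, an estimated correlation and leaving out each bird. The sample titles carry numbers whose meaning is not stated. Each diet has 2 birds numbered up to 25 and 2 above, and the 2 of a block have neighbouring numbers. Chosen after the data were seen were fits without diet H replicates 3 and 4, with named features only, with identical features kept once, with a trend on genomic span removed from each array, and fits within each title number block.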

Results

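Liver RNA of 16 male broiler chickens, a fast-growing meat type of Gallus gallus, was measured on 1-colour arrays at day 21. The birds had been fed 1 of 4 diets, which the labels name only by the letters A, E, F and H, with 4 birds per diet. The series title names 2 kinds of feed additive, a blend of plant essential oils and saponins, which are soap-like plant glycosides, and asks how they may act on growth and protein digestion. The labels used here do not say which letter stands for which supplement or for the unsupplemented feed, so diet A serves as the reference of the first 3 comparisons only as the first letter. Each array gave log2 signals for 20804 features, of which 12300 carried 1 gene symbol and stood for 11528 genes. Array medians lay between 6.11 and 6.21, and single values between 0.93 and 14.63. The number of arrays limits the precision: the median standard error of a difference between diets was 0.216 on the log2 scale, a 95% half-width of 0.458.

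Arrays of 1 diet were no more alike than arrays of different diets. The mean correlation of 2 arrays was 0.968 within a diet and 0.969 between diets. The cell cycle list, 48 genes of DNA replication and mitosis, had the widest span of medians over the birds, from -0.91 in diet F replicate 1 to 1.25 in diet E replicate 2, relative to the mean of the 16 arrays. Interferon response genes spanned 1.35, from -0.73 in diet H replicate 4 to 0.62 in diet E replicate 2. Diet H replicates 3 and 4 stood apart from the other 14 arrays, with a mean correlation with the rest of 0.948 and 0.946 against at least 0.966 in the others. In these 2 livers cytosolic ribosomal protein genes had a median 0.56 above that of the other 14 on the log2 scale, oxidative phosphorylation genes 0.56 above, circadian clock genes -0.63 and cell cycle genes -0.71 (-0.38 in replicate 3 and -0.82 in replicate 4). The first principal component held 43.1% of the variance, with scores of 68.9 and 73.2 for these 2 arrays, 38.9 for diet F replicate 4 and 29.2 for diet E replicate 1, against -31.6 to -2.76 in diet A. Across genes, the deviation of an array from the others went with the genomic span of the gene, a stand-in for transcript length: Spearman's rho was -0.354 and -0.363 for diet H replicates 3 and 4 and 0.331 for diet H replicate 2. Genes are not independent replicates, and these rho values describe single arrays.

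**Figure D1:**
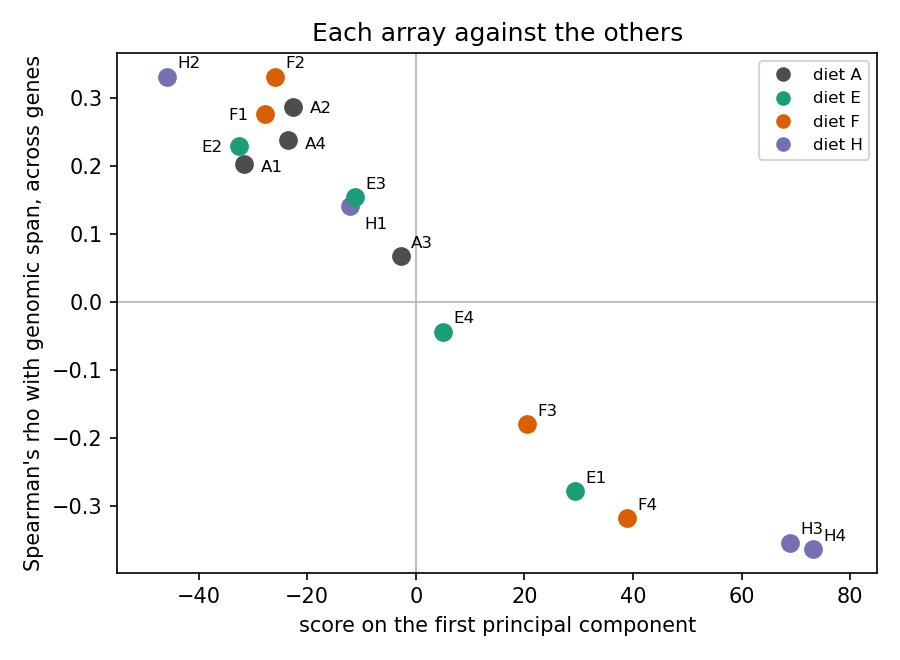
Each point is 1 array, coloured by diet and named by diet and replicate, with its score on the first principal component (43.1% of the variance) on the x axis and, on the y axis, Spearman's rho across genes between its deviation from the other arrays and genomic span. Diet H replicates 3 and 4 lie at scores of 68.9 and 73.2 with rho of -0.354 and -0.363, and diet H replicate 2 lies at the other end, at -45.8 and 0.331.

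Tested over all 4 diets at once, no feature passed. The 6 genes with the smallest p in limma's F test were MIR1661, SPATA1, PIK3C2G, ARRDC1, CA4 and UBAP1L, each at adjusted p = 0.984. PIK3C2G, a class II phosphoinositide 3-kinase, averaged 5.04 ± 0.37 (SD, n = 4) in diet A, 4.88 ± 0.26 in diet E, 4.37 ± 0.35 in diet F and 4.33 ± 0.11 in diet H. The microRNA gene MIR1661 lay under the 20th percentile of all signals on all 16 arrays. The F test called 0 of 20804 features after adjustment and 444 at an unadjusted p under 0.05, where chance gives 1040 on average.

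In diet E against diet A, 6 of the 33 gene lists tested shifted, all upward, in limma's camera test with a preset correlation between genes. A shift here and below means such a call. The preset of 0.01 lies far under the estimates of 0.66 for ribosomal protein, 0.66 for cell cycle and 0.44 for oxidative phosphorylation genes. Data simulated without a diet effect, at a later stage, called medians of 6 to 7 lists per comparison, and 58 of 100 data sets called at least 6 here. Oxidative phosphorylation genes, which build the respiratory chain and the ATP synthase, had a median log2 difference of 0.17 with 42 of 49 higher (adjusted p = 7.68e-05, and adjusted p = 0.914 with an estimated correlation). Markers of stellate cells and fibroblasts, the matrix-forming cells of the liver, had a median of 0.20 with 26 of 32 higher (adjusted p = 7.68e-05, and adjusted p = 0.390 with an estimated correlation). Markers of bile duct epithelium had a median of 0.16 with 15 of 19 higher (adjusted p = 0.000335, and adjusted p = 0.168 with an estimated correlation), and the proteasome list 0.14 with 24 of 28 higher (adjusted p = 0.000670, and adjusted p = 0.174 with an estimated correlation). Immediate early genes, which respond to stimuli within minutes, had a median of 0.15 with 16 of 22 higher (adjusted p = 0.00217, and adjusted p = 0.663 with an estimated correlation), and cell cycle genes 0.19 with 41 of 48 higher (adjusted p = 0.00533, and adjusted p = 0.915 with an estimated correlation).

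Among single genes the smallest p belonged to GSTZ1 (feature 15517195), which encodes the maleylacetoacetate isomerase of tyrosine breakdown. GSTZ1 averaged 10.4 ± 0.48 (SD, n = 4) in diet A and 11.2 ± 0.18 in diet E, a difference of 0.76 ± 0.20 (SE) or 1.70-fold, with adjusted p = 1. IL22RA1, a subunit of the interleukin-22 receptor, differed by 1.07 ± 0.33 and RAB23, a small GTPase, by 0.90 ± 0.28. LTBP1, which binds latent TGF-beta in the matrix, differed by 0.53 ± 0.15, KRT24 by 0.54 ± 0.16 and CGTL by -0.66 ± 0.18. NIM1K and MIR1661 also led by p, with signals under the 20th percentile in all 8 birds. In the immediate early list CYR61, a matrix-associated signalling protein, differed by 1.05 ± 0.31 (2.06-fold), DUSP1, a MAP kinase phosphatase, by 0.68 ± 0.22, and the transcription factor gene FOS by 0.71 ± 0.23. Of the bile duct markers ANXA13 differed by 0.77 ± 0.24, SPP1 by 0.69 ± 0.26 and CDH17 by 0.51 ± 0.26. Among the stellate cell and fibroblast markers, the collagen genes COL1A1 and COL6A2 differed by 0.67 ± 0.34 and 0.54 ± 0.25, and the protease inhibitor gene TIMP3 by 0.36 ± 0.16. PSMA6 and PSMB2 of the proteasome each differed by 0.26, with standard errors of 0.13 and 0.15, and ATP5B and NDUFA8 of the oxidative phosphorylation list by 0.29 ± 0.19 and 0.25 ± 0.17. ESCO2, GINS1 and MCM2 of the cell cycle list differed by 0.40 ± 0.17, 0.73 ± 0.32 and 0.66 ± 0.41, all at adjusted p = 1.

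limma called 0 of 20804 features between diets E and A and 423 at an unadjusted p under 0.05, with chance at 1040 on average. Data sets simulated without a diet effect had a median of 501.5. Of the 198 members of the 6 lists 0 passed over all features and 0 when adjusted over the list alone, with 12 at an unadjusted p under 0.05. The difference of diet E from diet A went with genomic span across genes at rho = -0.260. With a trend on genomic span taken out of each array, a setting chosen after the data were seen, the oxidative phosphorylation and immediate early medians were each 0.09. The cell cycle median was -0.12 without diet E replicate 2, and the list was not called without that bird or without diet A replicate 2 or 3 (0.04 and -0.006). Immediate early genes were not called without diet A replicate 4 or diet E replicate 4 (medians over the 8 omissions 0.13 to 0.24), and the other 4 lists were called in each of the 8. Their medians ran from 0.13 to 0.28 for bile duct markers (highest without diet A replicate 2), 0.13 to 0.26 for stellate cell and fibroblast markers (lowest without diet E replicate 1), 0.13 to 0.23 for oxidative phosphorylation genes and 0.11 to 0.18 for the proteasome. The sample titles carry numbers whose meaning is not stated, and each diet has 2 birds numbered up to 25 and 2 above. In the lower block of numbers the cell cycle median of diet E minus diet A was 0.96 and in the upper block -0.52. Without diet E replicate 2 the difference was 0.47 for GINS1 and 0.30 for MCM2, and without diet E replicate 4 that of NDUFA8 was 0.16.

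Diet F against diet A gave 4 shifted lists, again all upward, and 90 of 100 data sets simulated without a diet effect called at least as many. Cholesterol synthesis and uptake genes had a median log2 difference of 0.26 with 13 of 16 higher (adjusted p = 0.0123, and adjusted p = 0.8003 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.11 with 43 of 48 higher (adjusted p = 0.0123, and adjusted p = 0.8003 with an estimated correlation). Markers of intestine and pancreas had a median of 0.13 with 23 of 30 higher (adjusted p = 0.0123, and adjusted p = 0.8003 with an estimated correlation), and immediate early genes 0.18 with 16 of 22 higher (adjusted p = 0.0228, and adjusted p = 0.8003 with an estimated correlation).

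CYP51A1, the lanosterol demethylase of cholesterol synthesis, averaged 11.7 ± 0.32 (SD, n = 4) in diet A and 12.1 ± 0.40 in diet F, a difference of 0.45 ± 0.20 (SE) with adjusted p = 0.993. SREBF2, the transcription factor that drives the pathway, differed by 0.49 ± 0.25 and ACAT2 by 0.29 ± 0.17. The genes with the smallest p outside the lists included TMCC3 at -1.03 ± 0.32 (2.04-fold lower), SPATA1 at -0.76 ± 0.23 and PIK3C2G at -0.68 ± 0.20. FAM20B, a kinase that phosphorylates xylose in proteoglycans, differed by 0.49 ± 0.14, ECHDC2 by 0.58 ± 0.17, UBAP1L by 0.59 ± 0.18 and TKTL1, a transketolase-like protein, by 0.44 ± 0.14. MIR1661, CYP2AB3 and MIR30B also led by p, at signals under the 20th percentile in all 8 birds. RPL38, RPL4 and RPS29 differed by 0.30 ± 0.20, 0.20 ± 0.17 and 0.35 ± 0.32. DUSP1, CYR61 and FOS differed by 0.55 ± 0.22, 0.60 ± 0.31 and 0.40 ± 0.23. Of the pancreatic enzyme genes CTRC differed by 0.60 ± 0.29, CPB1 by 0.91 ± 0.45 and PNLIPRP1 by 0.79 ± 0.39, the last 2 under the 20th percentile in 4 and 7 of the 8 birds. All of these stood at adjusted p = 0.993.

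Between diets F and A limma called 0 of 20804 features and 349 at an unadjusted p under 0.05. Over the 116 members of the 4 lists 0 passed over all features and 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05. Across genes the difference went with genomic span at rho = -0.243. The number of lists called was 0 without diet A replicate 4 and 1 without diet F replicate 3. Over the 8 omissions the cholesterol median ran from 0.18 to 0.36, with no call without diet F replicate 1 either. The ribosomal, immediate early and intestine and pancreas medians ran from 0.03 to 0.16, 0.10 to 0.26 and 0.04 to 0.24, with calls that also ended without diet F replicate 4 and, for immediate early genes, diet A replicate 1. Quantile normalization gave 7 lists, and 2 remained after the trend on genomic span was taken out, with the ribosomal median then 0.02 and the immediate early median 0.15. In the lower title block the ribosomal median of diet F minus diet A was -0.05 and in the upper block 0.27, and those of immediate early genes were 0.04 and 0.31 and of intestine and pancreas markers 0.02 and 0.23. Without diet F replicate 4 the differences were 0.29 for CPB1, 0.28 for CTRC, 0.43 for PNLIPRP1, 0.35 for CYR61 and 0.24 for FOS. That of ACAT2 was 0.18 without diet F replicate 3, that of RPL38 0.18 without diet A replicate 4 and that of RPS29 0.20 without diet A replicate 1.

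In diet H against diet A, 5 lists shifted upward and 2 downward. Oxidative phosphorylation genes had a median log2 difference of 0.34 with 43 of 49 higher (adjusted p = 1.52e-08, and adjusted p = 0.646 with an estimated correlation), and cytosolic ribosomal protein genes 0.26 with 47 of 48 higher (adjusted p = 5.51e-08, and adjusted p = 0.646 with an estimated correlation). Circadian clock genes had a median of -0.39 with 11 of 15 lower (adjusted p = 0.0112, and adjusted p = 0.646 with an estimated correlation), and endoplasmic reticulum chaperone and stress genes, which serve protein folding, -0.35 with 22 of 31 lower (adjusted p = 0.0112, and adjusted p = 0.646 with an estimated correlation). Markers of T and NK cells had a median of 0.11 with 18 of 25 higher (adjusted p = 0.0231, and adjusted p = 0.646 with an estimated correlation). Immediate early genes had a median of 0.21 with 15 of 22 higher (adjusted p = 0.0236, and adjusted p = 0.646 with an estimated correlation), and markers of intestine and pancreas 0.24 with 23 of 30 higher (adjusted p = 0.0112, and adjusted p = 0.646 with an estimated correlation).

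Several of these shifts lay in diet H replicates 3 and 4, the 2 arrays that stood apart. With these 2 left out, a setting chosen after the data were seen, the median of oxidative phosphorylation genes in diet H minus diet A was 0.02, of ribosomal protein genes -0.06 and of circadian clock genes -0.03. Those of endoplasmic reticulum genes, immediate early genes and intestine and pancreas markers were -0.03, 0.12 and 0.04, and none of these 6 lists was called. T and NK cell markers then had a median of 0.36 (adjusted p = 2.34e-11, and adjusted p = 0.359 with an estimated correlation). Diet H was then 2 birds, and relative to the mean of the 16 arrays these markers lay at -0.002 in replicate 1 and 0.51 in replicate 2, against a diet A mean of -0.07. Interferon response genes, which were not called with all birds, had 0.42 in that setting (adjusted p = 5.42e-15, and adjusted p = 0.359 with an estimated correlation). Proteasome genes had 0.13 (adjusted p = 0.00122, and adjusted p = 0.365 with an estimated correlation), bile duct markers 0.21 (adjusted p = 0.0128, and adjusted p = 0.408 with an estimated correlation) and cell cycle genes 0.24 (adjusted p = 0.0455, and adjusted p = 0.905 with an estimated correlation). The cell cycle list lay at -0.45 in replicate 1 and 0.996 in replicate 2, and the interferon list at 0.42 and 0.45. Across genes the difference went with genomic span at rho = -0.344 with all birds and at 0.115 without these 2. The median span was 3265.5 bp for ribosomal protein genes, 3285 bp for oxidative phosphorylation genes and 35092 bp for circadian clock genes, against 16339.5 bp for all genes.

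Of the T and NK cell markers CD3D, part of the T cell receptor complex, averaged 6.95 ± 0.13 (SD, n = 4) in diet A and 7.66 ± 0.36 in diet H, a difference of 0.71 ± 0.20 (SE) or 1.63-fold with adjusted p = 0.521. CD8A differed by 0.63 ± 0.24 and the T-box factor gene EOMES by 0.58 ± 0.24. GBP4L, of the interferon-inducible guanylate-binding protein family, differed by 1.05 ± 0.29 (2.07-fold), and was above the diet A mean in 4 of 4 birds. Among the clock genes ARNTL, a core activator, differed by -0.58 ± 0.19, the repressor gene CRY1 by -0.71 ± 0.26 and NFIL3 by -1.18 ± 0.48. NFIL3 read 7.67 and 7.64 in diet H replicates 3 and 4 and 8.93 and 9.77 in replicates 1 and 2. PDIA4, a protein disulfide isomerase, differed by -0.74 ± 0.29, with 9.71 and 9.83 in replicates 3 and 4 and 10.7 and 11.2 in replicates 1 and 2. ERN1, a sensor of unfolded proteins, differed by -0.48 ± 0.17 and CRELD2 by -0.61 ± 0.28. APOA4, an apolipoprotein counted here among the intestinal markers, differed by 1.19 ± 0.47, with 10.8 and 11.1 in replicates 3 and 4 against 8.93 and 9.53 in replicates 1 and 2.

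Further genes led by p alone. TUBB3, a tubulin, differed by 0.87 ± 0.22 and TRIB1, a pseudokinase of hepatic lipid regulation, by 0.72 ± 0.18. ARRDC1 differed by 0.70 ± 0.17, UBAP1L by 0.70 ± 0.18, RAD51D, a DNA repair gene, by 0.68 ± 0.18 and SUPT4H1, a transcription elongation factor gene, by 0.78 ± 0.21. SPATA1, KDELC2 and the microRNA gene MIR1551 lay lower, at -0.92 ± 0.23, -0.72 ± 0.19 and -0.78 ± 0.19. RPL38, RPS3 and RPS14 differed by 0.52 ± 0.20, 0.33 ± 0.15 and 0.36 ± 0.17, and ATP5E and ATP5B by 0.55 ± 0.22 and 0.47 ± 0.19. DUSP1 differed by 0.79 ± 0.22, CYR61 by 0.81 ± 0.31 and RHOB by 0.42 ± 0.19. SLC5A1, an intestinal glucose transporter gene, differed by 0.50 ± 0.22. Each of these genes stood at adjusted p = 0.521.

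limma called 0 of 20804 features between diets H and A, and 1708 at an unadjusted p under 0.05 (923 higher, 785 lower), where chance gives 1040 on average. With genes that vary together such counts spread widely. Of 100 data sets simulated without a diet effect 19 reached 1708, with a median of 417.5 and a 95th percentile of 6101.7. Of 220 list members 0 passed over all features and 0 when adjusted over the list alone, with 33 at an unadjusted p under 0.05. With 1 bird left out, the ribosomal median ran from 0.14 without diet H replicate 4 to 0.42 without diet H replicate 2, and the oxidative phosphorylation median from 0.22 without diet H replicate 4 to 0.48. Intestine and pancreas markers ran from 0.13 without diet H replicate 3 to 0.36 and circadian clock genes from -0.54 to -0.27, and these 4 lists were called in each of the 8 fits. The endoplasmic reticulum call ended without diet A replicate 2 or 3 (medians over the 8 omissions -0.37 to -0.19), the immediate early call without diet A replicate 1 or 4 or diet H replicate 2 (0.15 to 0.26) and the T and NK cell call without diet H replicate 2 (0.07 to 0.30). The unadjusted count was 468 without diet H replicates 3 and 4. With the span trend taken out, the ribosomal and immediate early calls ended, at medians of 0.07 and 0.06, and the oxidative phosphorylation median was 0.15. Without diet A replicate 2 the difference of NFIL3 was -0.77, and without diet H replicate 3 that of CRELD2 was -0.38. In the lower title block the ribosomal, oxidative phosphorylation and interferon medians of diet H minus diet A were -0.08, 0.09 and 0.40, and in the upper block, which holds diet H replicates 3 and 4, they were 0.61, 0.56 and -0.44. A fit of the upper block alone, with 2 birds per diet, called 5472 of 20804 features, 23 of the 31 genes named for this comparison among them (lower block 0, with 511 at an unadjusted p under 0.05). These genes were named from the fit of all birds, which holds the same birds, so their recurrence is no independent support. The fit of all birds with the block as a covariate called 0, with 3175 at an unadjusted p under 0.05.

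**Figure D2:**
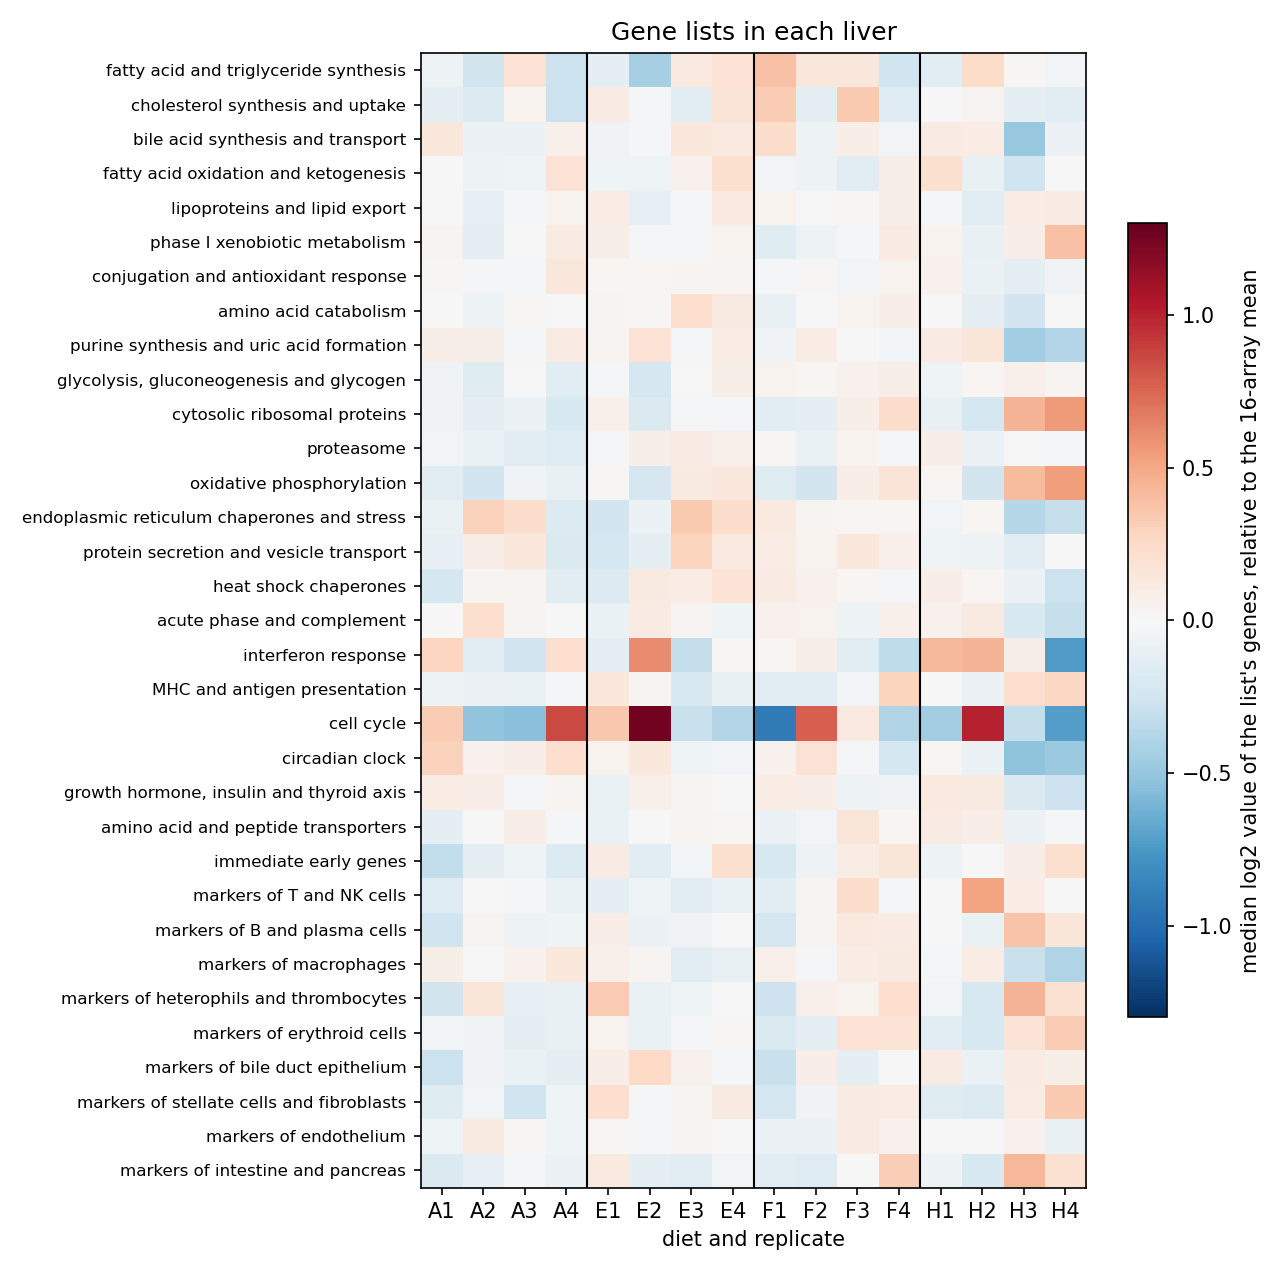
Each column is 1 bird, named by diet and replicate, and each line of cells is 1 of the 33 gene lists, coloured by the median log2 value of its genes relative to the mean of the 16 arrays. The ribosomal and oxidative phosphorylation lists are highest in diet H replicates 3 and 4, and the cell cycle list runs from -0.91 in diet F replicate 1 to 1.25 in diet E replicate 2.

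Between diets E and F, 8 lists shifted. Cell cycle genes had a median log2 difference of 0.41 with 43 of 48 higher in diet E (adjusted p = 8.17e-08, and adjusted p = 0.615 with an estimated correlation), and interferon response genes 0.24 with 32 of 39 higher (adjusted p = 0.000133, and adjusted p = 0.586 with an estimated correlation). Bile duct markers had a median of 0.17 with 15 of 19 higher (adjusted p = 0.000434, and adjusted p = 0.184 with an estimated correlation). Fatty acid and triglyceride synthesis genes had a median of -0.13 with 18 of 21 lower in diet E (adjusted p = 0.0216, and adjusted p = 0.586 with an estimated correlation). The bird-to-bird spread of the cell cycle list was larger than this shift: its medians averaged 0.23 ± 0.75 (SD, n = 4) in diet E and -0.10 ± 0.72 in diet F.

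Smaller shifts were found for amino acid catabolism genes, at 0.05 with 34 of 55 higher (adjusted p = 0.0167, and adjusted p = 0.586 with an estimated correlation), and for markers of stellate cells and fibroblasts, at 0.08 with 23 of 32 higher (adjusted p = 0.0167, and adjusted p = 0.586 with an estimated correlation). T and NK cell markers lay at -0.12 with 21 of 25 lower (adjusted p = 0.0216, and adjusted p = 0.615 with an estimated correlation), and macrophage markers at -0.08 with 17 of 21 lower (adjusted p = 0.0260, and adjusted p = 0.586 with an estimated correlation). CA4, which encodes the membrane-bound carbonic anhydrase IV, had the smallest p, at 8.57 ± 0.80 (SD, n = 4) in diet E and 10.1 ± 0.62 in diet F, a difference of -1.52 ± 0.41 (SE) or 2.86-fold lower, with adjusted p = 1. MSMB differed by 0.92 ± 0.32, TIMP3 by 0.48 ± 0.16, the splicing factor gene SRSF7 by -0.40 ± 0.13 and the microRNA gene MIR2129 by -0.43 ± 0.14. MIR103A1 lay under the 20th percentile in all 8 birds. ACSS2, which makes acetyl-CoA from acetate, differed by -0.46 ± 0.28 and MID1IP1, an activator of fatty acid synthesis, by -0.32 ± 0.23. GSTZ1 and SDSL of amino acid catabolism differed by 0.47 ± 0.20 and 0.44 ± 0.18. MCM2, a part of the replicative helicase, differed by 0.74 ± 0.41 and the interferon-induced genes OASL and IFI35 by 0.61 ± 0.35 and 0.25 ± 0.17. CDH17 and ANXA13 of the bile duct list differed by 0.65 ± 0.26 and 0.54 ± 0.24, PDGFRA of the fibroblast list by 0.43 ± 0.19, CD247 of the T cell list by -0.17 ± 0.15 and LY86 of the macrophage list by -0.22 ± 0.16, each at adjusted p = 1.

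limma called 0 of 20804 features between diets E and F and 281 at an unadjusted p under 0.05. Of 260 list members 0 passed over all features and 0 when adjusted over the list alone, with 8 at an unadjusted p under 0.05. Without diet E replicate 2 the cell cycle median was 0.02 and the interferon median -0.02, and neither list was called. The cell cycle, bile duct and stellate cell calls ended without diet F replicate 1, the last also without diet E replicate 1 (medians over the 8 omissions -0.03 to 0.15). The interferon median was 0.08 without diet F replicate 4. Fatty acid synthesis (-0.24 to -0.03) and amino acid catabolism (0.03 to 0.09) were called in 4 of the 8 omissions, and T and NK cell (-0.19 to -0.04) and macrophage markers (-0.15 to -0.08) in 3. In the lower title block the cell cycle median of diet E minus diet F was 0.92 and in the upper block -0.15, and the interferon medians were 0.27 and 0.17. The lower and upper medians also lay on opposite sides of 0 for fatty acid synthesis genes (-0.41 and 0.18), T and NK cell markers (0.03 and -0.29), macrophage markers (0.11 and -0.21) and stellate cell and fibroblast markers (0.24 and -0.04). Without diet E replicate 2 the differences were -0.24 for ACSS2, 0.30 for OASL, 0.13 for IFI35 and 0.38 for MCM2. Without diet F replicate 1 that of LY86 was -0.11 and that of CD247 -0.29, and without diet F replicate 3 that of CD247 was -0.09. Without diet F replicate 4 that of MID1IP1 was -0.15.

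**Figure D3:**
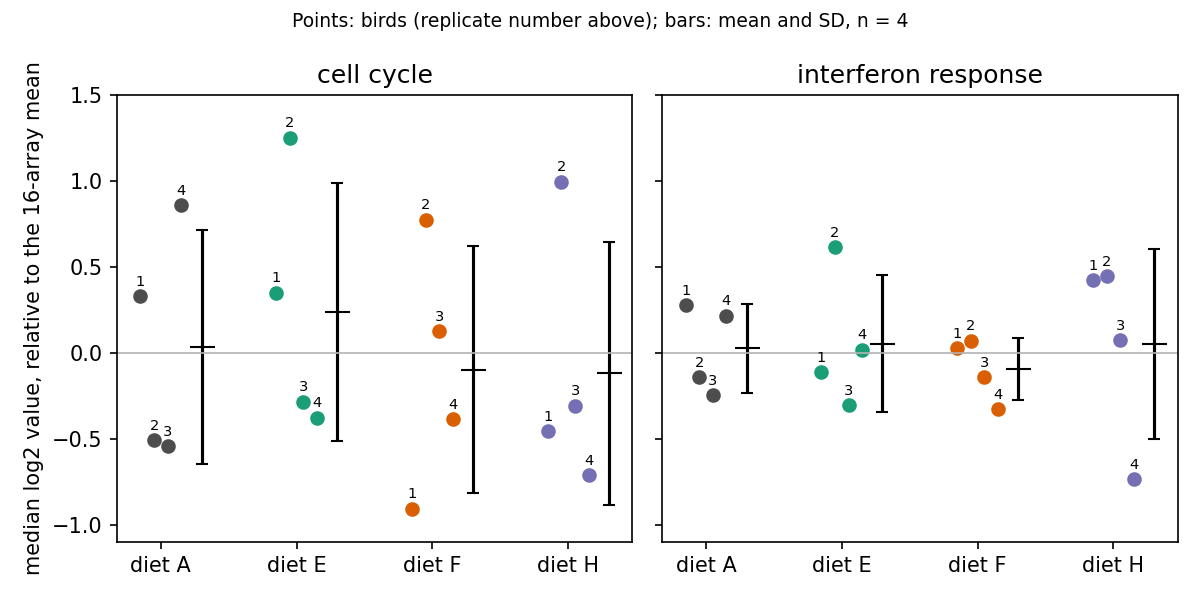
Each point is 1 bird, with its replicate number, and shows the median log2 value of the cell cycle genes (left panel) or interferon response genes (right panel) relative to the mean of the 16 arrays, and bars give the mean and SD of the 4 birds of a diet. The birds of each diet spread over more than the distance between diet means, which for the cell cycle list run from -0.12 in diet H to 0.23 in diet E.

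Diet H against diet E gave 4 lists shifted upward and 4 downward. Ribosomal protein genes had a median log2 difference of 0.20 with 46 of 48 higher in diet H (adjusted p = 3.69e-09, and adjusted p = 0.849 with an estimated correlation), and oxidative phosphorylation genes 0.16 with 41 of 49 higher (adjusted p = 9.24e-05, and adjusted p = 0.849 with an estimated correlation). Amino acid catabolism genes had a median of -0.21 with 39 of 55 lower (adjusted p = 0.000199, and adjusted p = 0.790 with an estimated correlation). T and NK cell markers had a median of 0.16 with 18 of 25 higher (adjusted p = 0.000289, and adjusted p = 0.849 with an estimated correlation). In single genes CYP7A1 (feature 15462286), the rate-limiting enzyme of bile acid synthesis, averaged 11.3 ± 0.22 (SD, n = 4) in diet E and 9.77 ± 0.76 in diet H, a difference of -1.49 ± 0.38 (SE) or 2.81-fold lower, with adjusted p = 0.942 over all features and 0.0250 when adjusted over the list alone.

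CYP7A1 was the 1 gene of the 23 in the bile acid list to pass in that way, and no member of the other lists did so in any of the 6 comparisons, over which the adjustment did not extend. Its signal in diet H was 9.43, 10.71, 8.95 and 10.01 in replicates 1 to 4, and the 4 diet E birds lay between 10.95 and 11.47. In diets A and F it averaged 10.9 ± 0.74 and 10.8 ± 0.47 (SD, n = 4). The remaining shifts were those of cell cycle genes at -0.36 with 41 of 48 lower (adjusted p = 0.00287, and adjusted p = 0.887 with an estimated correlation) and endoplasmic reticulum genes at -0.24 with 24 of 31 lower (adjusted p = 0.00873, and adjusted p = 0.849 with an estimated correlation). Intestine and pancreas markers lay at 0.12 with 26 of 30 higher (adjusted p = 0.0129, and adjusted p = 0.849 with an estimated correlation). Genes of purine synthesis and uric acid formation, the route by which birds excrete nitrogen, lay at -0.21 with 15 of 21 lower (adjusted p = 0.0228, and adjusted p = 0.849 with an estimated correlation). AGXT2, an aminotransferase of amino acid breakdown, differed by -0.98 ± 0.27 and KYNU by -0.91 ± 0.39, PAICS and PPAT of purine synthesis by -0.59 ± 0.21 and -0.73 ± 0.27, and DPP4, a dipeptidyl peptidase, by -0.99 ± 0.29. ATOH7 and TGFB2 differed by -0.77 ± 0.19 and -0.48 ± 0.14, and LIX1 lay under the 20th percentile in all 8 birds. CD3D and CD247 differed by 0.47 ± 0.20 and 0.39 ± 0.15, COX6C by 0.41 ± 0.18, RPL29 and RPL7 by 0.34 ± 0.17 and 0.25 ± 0.13, and the chaperone gene PDIA6 by -0.45 ± 0.19, each at adjusted p = 0.942.

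limma called 0 of 20804 features between diets H and E and 566 at an unadjusted p under 0.05. Of the 307 members of the 8 lists 0 passed over all features and 0 when adjusted over the list alone, with 14 at an unadjusted p under 0.05. Without diet H replicates 3 and 4 the medians of diet H minus diet E were -0.10 for ribosomal protein genes, -0.13 for oxidative phosphorylation genes and 0.04 for purine synthesis genes. Intestine and pancreas markers then had -0.12 and T and NK cell markers 0.39, the latter far higher in replicate 2 of diet H than in replicate 1, and rho with genomic span moved from -0.276 to 0.289. In that setting ribosomal protein genes were called downward (adjusted p = 0.00526, and adjusted p = 0.952 with an estimated correlation), as were oxidative phosphorylation genes (adjusted p = 0.0127, and adjusted p = 0.952 with an estimated correlation). Interferon response genes had a median of 0.32 there (adjusted p = 6.04e-06, and adjusted p = 0.826 with an estimated correlation) and stellate cell and fibroblast markers -0.28 (adjusted p = 0.00526, and adjusted p = 0.826 with an estimated correlation). With 1 bird left out the ribosomal median ran from 0.07 without diet H replicate 4 to 0.32 without diet H replicate 2, and that of amino acid catabolism from -0.29 to -0.12, the latter without diet H replicate 3, and both lists were called in each of the 8 fits. The cell cycle, endoplasmic reticulum, intestine and pancreas and purine calls held in 4, 5, 5 and 4 of the 8 fits without 1 bird, with medians of -0.77 to -0.02, -0.30 to -0.08, 0.05 to 0.25 and -0.31 to -0.06. The T and NK cell call ended without diet H replicate 2 (0.11) and the oxidative phosphorylation call without diet H replicate 4 (0.05). The cell cycle median was -0.02 without diet E replicate 2. In the lower title block the ribosomal and oxidative phosphorylation medians were -0.09 and -0.03, and in the upper block 0.49 and 0.34. A fit of the upper block called 4008 of 20804 features and 10 of the 21 genes named for this comparison, CYP7A1 among them. Those genes were named from a fit that holds the same birds, so this is no independent support. The lower and upper medians also lay on opposite sides of 0 for endoplasmic reticulum genes (0.16 and -0.51), purine synthesis genes (0.02 and -0.46) and intestine and pancreas markers (-0.12 and 0.47), and those of amino acid catabolism were -0.03 and -0.43. With the span trend taken out the purine call ended, at -0.15, and the ribosomal and oxidative phosphorylation medians were 0.10 and 0.06. Without diet H replicate 3, in which KYNU read 6.04, the differences were -0.37 for KYNU, -0.37 for PAICS and -0.44 for PPAT.

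Diet H against diet F gave 7 shifted lists. Interferon response genes had a median log2 difference of 0.24 with 33 of 39 higher in diet H (adjusted p = 8.08e-07, and adjusted p = 0.741 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.20 with 42 of 49 higher (adjusted p = 2.88e-09, and adjusted p = 0.741 with an estimated correlation), and ribosomal protein genes 0.18 with 46 of 48 higher (adjusted p = 8.08e-07, and adjusted p = 0.773 with an estimated correlation). Endoplasmic reticulum genes lay at -0.25 with 27 of 31 lower (adjusted p = 0.000266, and adjusted p = 0.741 with an estimated correlation), and genes of protein secretion and vesicle transport at -0.14 with 33 of 47 lower (adjusted p = 0.0154, and adjusted p = 0.773 with an estimated correlation). Macrophage markers lay at -0.24 with 15 of 21 lower (adjusted p = 0.0240, and adjusted p = 0.741 with an estimated correlation), and bile duct markers at 0.08 with 12 of 19 higher (adjusted p = 0.0452, and adjusted p = 0.741 with an estimated correlation).

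The interferon-induced gene IFI6 averaged 9.33 ± 0.61 (SD, n = 4) in diet F and 10.7 ± 0.88 in diet H, a difference of 1.32 ± 0.55 (SE) or 2.50-fold with adjusted p = 0.971, and TAP2, a peptide transporter of antigen presentation, differed by 0.46 ± 0.18. NPC1, which moves cholesterol out of lysosomes, differed by -0.54 ± 0.16, VEGFC, a growth factor of lymphatic vessels, by -0.59 ± 0.18 and the Wnt receptor gene FZD6 by -0.88 ± 0.26. SNTG2, GCG and LIX1 also led by p at signals under the 20th percentile in all 8 birds. LY86 and TLR4 of the macrophage list differed by -0.50 ± 0.16 and -0.34 ± 0.16, HSPA5 and PDIA6 of the chaperone list by -0.39 ± 0.20 and -0.40 ± 0.19, and SEC16A and SEC13 of the secretory pathway by -0.40 ± 0.16 and -0.31 ± 0.15. COX6C and ATP5H differed by 0.46 ± 0.18 and 0.44 ± 0.18, RPL32 by 0.30 ± 0.18, and CDH17 and SLC5A1 of the bile duct list by 0.48 ± 0.26 and 0.48 ± 0.22. All of these genes had adjusted p = 0.971.

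limma called 0 of 20804 features between diets H and F and 540 at an unadjusted p under 0.05. Of 254 list members 0 passed over all features and 0 when adjusted over the list alone, with 13 at an unadjusted p under 0.05. Without diet H replicates 3 and 4 the medians of diet H minus diet F were -0.14 for ribosomal protein genes, -0.06 for oxidative phosphorylation genes, -0.04 for endoplasmic reticulum genes and -0.01 for macrophage markers. The ribosomal list was called downward (adjusted p = 0.000168, and adjusted p = 0.848 with an estimated correlation). Interferon response genes had 0.59 (adjusted p = 2.32e-12, and adjusted p = 0.848 with an estimated correlation). T and NK cell markers had 0.24 (adjusted p = 0.00202, and adjusted p = 0.848 with an estimated correlation) and cell cycle genes 0.42 (adjusted p = 0.0242, and adjusted p = 0.848 with an estimated correlation), both lists far higher in replicate 2 of diet H than in replicate 1. These were the 4 lists called in that setting, and rho with genomic span moved from -0.297 to 0.265. The interferon median was 0.40 in the lower title block and -0.02 in the upper one, the ribosomal medians were -0.01 and 0.34 and the macrophage medians 0.01 and -0.32. With the span trend taken out the ribosomal and bile duct calls ended, at 0.05 and 0.09, and the oxidative phosphorylation median was 0.11. Without diet H replicate 3 the differences were 0.20 for RPL32 and -0.22 for TLR4, and without diet F replicate 1 they were 0.27 for SLC5A1 and 0.31 for CDH17, the latter 0.30 without diet H replicate 2. The interferon call ended without diet H replicate 2 (median 0.11), and the ribosomal call without diet H replicate 4 (0.03). Oxidative phosphorylation and endoplasmic reticulum genes were called in each of the 8 fits, with medians of 0.08, without diet H replicate 4, to 0.34 and of -0.31 to -0.12, the latter without diet H replicate 3. The secretion, macrophage and bile duct calls held in 4, 3 and 2 of the 8 fits without 1 bird, with medians of -0.17 to -0.10, -0.36 to -0.08 and 0.02 to 0.21.

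The other 15 lists were called in none of the 6 comparisons. Bile acid synthesis and transport had medians from -0.13 to 0.08, fatty acid oxidation and ketogenesis from -0.14 to 0.07, lipoproteins and lipid export from -0.07 to 0.06, and glycolysis, gluconeogenesis and glycogen from -0.07 to 0.12. Phase I xenobiotic metabolism, which holds cytochrome P450 genes that act on foreign compounds, ranged from 0.03 to 0.07 over 24 genes (smallest adjusted p = 0.445), and conjugation and antioxidant response from -0.06 to 0.06 over 45 genes (smallest adjusted p = 0.192). The growth hormone, insulin and thyroid axis ranged from -0.12 to 0.02, amino acid and peptide transporters from -0.12 to -0.01, acute phase and complement from -0.13 to -0.02 and MHC and antigen presentation from -0.06 to 0.18. Heat shock chaperones came nearest to a call, with medians from -0.105 to 0.12 (smallest adjusted p = 0.0698). Markers of B and plasma cells ranged from -0.04 to 0.16, of heterophils and thrombocytes from 0.02 to 0.23, of erythroid cells from -0.04 to 0.07 and of endothelium from -0.02 to 0.05. Of the W chromosome list HINTW alone was measured, at 4.15 to 5.43 on the 16 arrays of males, so that list was not tested.

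The differences of diets E, F and H from diet A resembled each other across features. The correlation was 0.638 between E and F, 0.654 between E and H and 0.690 between F and H, over 20804 features that are not independent replicates. These comparisons share the diet A birds, and simulated diets without an effect gave mean correlations of 0.510, 0.516 and 0.509, with 95% ranges of -0.160 to 0.882, -0.190 to 0.936 and -0.200 to 0.918. The covariances were 0.0365, 0.0527 and 0.0573, against simulated means of 0.0449, 0.0433 and 0.0463. With the diet A birds split 2 and 2, the correlations were 0.158, 0.274 and 0.311. Without diet H replicates 3 and 4 those of E with H and of F with H were 0.243 and 0.187 with all diet A birds.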

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

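Tests chosen only after the result was seen were those of diet H acting alike on its 4 birds, of the title number block, of genomic span as the whole cause, of markers of other cells beside the cell cycle list, of the cell cycle and interferon lists together and of title neighbours, and the fits within title blocks and without diet H replicates 3 and 4.

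Diet H replicates 3 and 4 lay apart from the other 14 arrays on a first component with 43.1% of the variance. Unequal value distributions are argued against, since quantile normalization left 42.5% with the same 2 arrays lowest in correlation. A diet effect alike on the 4 birds would not set 2 of them apart, so its test could only restate the pattern. The lowest diet H score was -45.79, under every diet A score. A loss of long transcripts, as RNA breakdown might give, predicted in advance that the difference would fall with gene length, and rho with genomic span was -0.378 over 11030 genes (95.7%) and -0.066 to -0.484 in 5 bins of level, yet as the whole cause it is argued against, since removing that trend left 49.63% of the variance against 53.99% before. The title number block stays open: its scores differed within diets (exact permutation p = 0.0216, 1296 arrangements), by 13.96 in diet A, 56.4 in diet F and 100 in diet H but -1.34 in diet E. In diet H the upper block is replicates 3 and 4, the arrays that prompted the test, so this p is not independent of the pattern. The bound for this test was also narrowed after its p was seen. With 2 birds of each diet in a block, the block cannot be told apart from the birds themselves. A biological difference of these 2 birds, such as feeding state, was not tested, and neither was an effect of diet H on part of its birds.

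The cell cycle list ranged over 2.16 on the log2 scale across the 16 birds, with an SD within diets of 0.68 to 0.76. Array noise independent between genes is argued against, since the widest range among 1000 random lists of 48 genes with like means was 0.630. Random lists hold unrelated genes, so array noise shared by the genes of this list was not tested. More cells of another type could not be settled: with diet means removed, T and NK cell markers had the highest Pearson's r of the marker lists, 0.540 (permutation p = 0.0270, adjusted p = 0.135 in a family of 10; rho = 0.421, p = 0.108, adjusted p = 0.360; r within title blocks 0.665 and 0.174). Macrophage markers had r = 0.502 (permutation p = 0.0483, adjusted p = 0.161) and the higher rho, 0.509 (p = 0.0469, adjusted p = 0.234). Their r was 0.041 in the lower title block and 0.624 in the upper one. The 2 birds farthest from the cell cycle median were diet E replicate 2 and diet H replicate 2, both in the lower block. Without the 2 farthest birds r was 0.196 for T and NK cell and 0.188 for macrophage markers. Leaving out the birds with the most extreme cell cycle values also narrows the range, which can itself lower r. Whether the T and NK cell or the macrophage relation rested on those birds was thus not settled. Interferon response genes went with the cell cycle list at r = 0.647 (p = 0.00602, adjusted p = 0.0602; rho = 0.621, p = 0.0118, adjusted p = 0.118), at 0.410 without the 2 farthest birds, 0.522 and 0.670 within title blocks, and at 0.6476 (p = 0.0114) without diet H replicates 3 and 4, so the relation did not rest on those 2 arrays but failed the adjustment. As a hypothesis, livers may have differed in proliferation or in a recent immune stimulus, which was not tested. Beyond diet, the marker lists and the interferon list, no biological explanation was examined.

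Over the 4 diets, 4 of the 81 ways of pairing the birds within diets gave correlations as high as pairs with neighbouring title numbers (one-sided exact permutation p = 0.0494). The test measures the same likeness as the consensus correlation of 0.432 that prompted it, so it does not exclude chance, and the bound for excluding chance was tightened after both p were seen. Without diet H the p was 0.1481 over 27 pairings, so the pair of arrays that lies apart in diet H may account for the result. The correlation of neighbours, diet means removed, was -0.296 in diet A and -0.313 in diet E, the middle of the 3 pairings in each, and 0.118 in diet F and 0.426 in diet H, the highest. Whether neighbours shared a pen is not stated, and no biological explanation was tested.

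Single birds lay far from the other 3 of their diet in 15 of 412 groups of 4 examined; chance flags about 1 in 20 groups, here 21. Among genes these were MIR1661 in diet A replicate 3 (2.73) and diet F replicate 3 (3.87), ATP5B in diet E replicate 2 (11.58), GINS1 in diet A replicate 4 (5.19), SPATA1 in diet F replicate 4 (4.47) and PNLIPRP1 in diet F replicate 4 (5.31). ARRDC1 was low in diet F replicate 1 (6.44) and diet H replicate 2 (7.09), TRIB1 in diet H replicate 1 (7.97) and COX6C in diet H replicate 2 (9.57), and CD247 was high in diet H replicate 2 (7.18). The median of the endoplasmic reticulum list was 0.129 in diet F replicate 1, and that of the acute phase and complement list 0.219 in diet A replicate 2 and -0.0684 in diet F replicate 3. The mean correlation of diet A replicate 3 with the other arrays was 0.976.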

How the results depend on the processing

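Alternatives chosen only after the data were seen were those without diet H replicates 3 and 4, with the span trend removed, with named features, with identical features kept once and within title blocks. The number of features past adjustment was 0 in the 7 tests under the alternatives run, leaving out each bird included (0 to 0), with 2 kinds of exception. Fits of the upper title block alone, with 2 birds per diet, called 5472 in H minus A, 4008 in H minus E and 1 in F minus A, GIMAP6 (2.31 ± 0.17, adjusted p = 0.0301, named after its values were seen), and 23 and 10 of the genes named for H minus A and H minus E were among those called. The diet H birds of that block are replicates 3 and 4, and the genes were named from a fit that holds the same birds. There was also 1 in diet E minus diet A with array quality weights, an unnamed dim feature (15380829) at -1.04 ± 0.14, adjusted p = 0.0384, named after its values were seen. At an unadjusted p under 0.05 diet H minus diet A gave 1708 features, 534 to 6291 with a bird left out, 468 without diet H replicates 3 and 4, 3635 with weights, 3175 with the title block and 429 with title neighbours as a random block. Outside the title block fits no named gene was called under the alternatives of the first set. With an estimated correlation the number of lists was 0 in E minus A, 0 in F minus A, 0 in H minus A, 0 in E minus F, 0 in H minus E and 0 in H minus F. Lists in F minus A were 7 with quantile normalization and 2 with the span trend removed, and in H minus F 4 without diet H replicates 3 and 4. With 1 bird left out lists numbered 5 to 12 in E minus A, 0 to 10 in F minus A (0 without diet A replicate 4, 1 without diet F replicate 3), 5 to 12 in H minus A, 5 to 9 in E minus F, 5 to 10 in H minus E and 3 to 11 in H minus F. All 40 list calls held with the title block and with the mean of a gene's features, 39 with quantile normalization and 39 with median centring (bile duct markers in H minus F at 0.07 were lost in both), 33 with the span trend removed (lost were ribosomal protein genes in F minus A, 0.02, H minus A, 0.07, and H minus F, 0.05, immediate early genes in F minus A, 0.15, and H minus A, 0.06, purine synthesis in H minus E, -0.15, and bile duct markers in H minus F, 0.09) and 22 without diet H replicates 3 and 4. These 22 are the 18 of comparisons that do not involve diet H and 4 of the 22 that do: T and NK cell markers in H minus A and H minus E, amino acid catabolism in H minus E and interferon response in H minus F. The T and NK cell calls ended without diet H replicate 2 with the other birds kept (medians 0.07 in H minus A and 0.11 in H minus E). Of the 40 calls 12 held in every fit without 1 bird, with medians that single birds moved by over 1.5-fold in several. Of those that compare diet H, amino acid catabolism in H minus E also held with diet H replicates 3 and 4 both out. Oxidative phosphorylation, circadian clock genes and intestine and pancreas markers in H minus A (0.02, -0.03 and 0.04) and endoplasmic reticulum genes in H minus F (-0.04) were then not called, and the others reversed. Without these 2 birds the direction reversed for ribosomal protein genes in H minus A (-0.058), H minus E (-0.096) and H minus F (-0.142), oxidative phosphorylation genes in H minus E (-0.135) and H minus F (-0.063), and purine synthesis (0.037) and intestine and pancreas markers (-0.116) in H minus E. The medians of endoplasmic reticulum (0.01) and cell cycle genes (0.07) in H minus E changed sign as well, and neither list was called. Without diet E replicate 2 it reversed for cell cycle genes in E minus A (-0.124; -0.12 to 0.48 over all omissions), and in H minus E the direction of the test turned while the median shrank to -0.019 without a change of sign (-0.77 to -0.02). In E minus F the interferon median was -0.019 without diet E replicate 2 and the stellate cell and fibroblast median -0.034 without diet F replicate 1, and neither list was called there. The correlations of differences from diet A, 0.638, 0.654 and 0.690, were 0.158, 0.274 and 0.311 with the diet A birds split, which the shared birds account for in part, and 0.243 (E with H) and 0.187 (F with H) without diet H replicates 3 and 4. Apart from these constructions the cause was not tested. No paired analysis was possible because the labels match no bird of one diet to a bird of another. The title numbers served only as blocks, in the fits given above. How far signals lay above background was not known, so dim features are the least certain.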

Other observations

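Of the tests here, the simulated data sets without a diet effect, the fits within title blocks and the blocked title effect were chosen only after the list results were seen.

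Genes of nitrogen and bile acid metabolism had some of their lowest values in single birds of diet H. The median of the bile acid list was -0.49 in diet H replicate 3 against -0.07 to 0.23 in the other 15 birds, and the median of the purine and uric acid list relative to the other arrays was -0.49 in diet H replicate 3 and -0.43 in diet H replicate 4. Relative to the other arrays, markers of heterophils and thrombocytes lay at 0.48 in diet H replicate 3 and 0.25 in replicate 4, of erythroid cells at 0.22 and 0.39, of B and plasma cells at 0.42 and 0.18 and of macrophages at -0.31 and -0.46. The phase I xenobiotic list lay at 0.11 and 0.43 and the MHC and antigen presentation list at 0.29 and 0.30.

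Chance was not excluded for the numbers of lists by other splits of the same birds. For features past adjustment the counts of splits decide nothing, since the diets called 0 and each of the 35 splits of a pair of diets, like each of the 100 random regroupings in the F test, reaches 0 by construction. The splits other than the real one had highest other counts of 1 in E minus A, 0 in F minus A, 1 in H minus A, 4 in E minus F, 6149 in H minus E and 9016 in H minus F. In the F test the highest other count was 1. For lists, 21 of 35 splits gave at least the real 6 in E minus A (highest other 12), 30 at least 4 in F minus A (13) and 18 at least 7 in H minus A (15). Likewise 13 gave at least 8 in E minus F (14), 13 at least 8 in H minus E (11) and 18 at least 7 in H minus F (11). For features at an unadjusted p under 0.05 in H minus A, 12 of 35 splits reached the real 1708 (highest other 6884). The split with 9016 features sets replicates 1 and 2 of diets F and H against replicates 3 and 4, which is the title number block, and with that block as a covariate H minus F gave 0 features (762 at an unadjusted p under 0.05). Splits along the title block called 12, 2, 6, 9, 6 and 4 lists in E minus A, F minus A, H minus A, E minus F, H minus E and H minus F, more than the real 6 and 8 in E minus A and E minus F, where the diets with the block as a covariate called 6 and 9. In H minus A that split gave 5586 features at an unadjusted p under 0.05, where the covariate gave 3175. The split with 6149 sets diet E replicates 1 and 4 and diet H replicates 3 and 4 against the others. Splits that call many features where the diets call 0 point to a structure of the samples other than diet.

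The title number block itself, tested over all 16 birds in limma beside the diets, gave 0 features past adjustment (smallest adjusted p = 0.0615) and 6566 at an unadjusted p under 0.05, with 4 lists at the preset correlation and 0 with an estimated one. Of 100 data sets simulated without a diet effect, 58, 90, 38, 44, 27 and 48 called at least as many lists as E minus A, F minus A, H minus A, E minus F, H minus E and H minus F, with medians of 6 to 7 lists, and 19 reached the unadjusted count of H minus A.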
